A study of Homo sapiens with 6 samples.

How the data were processed

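RNA sequencing libraries of U2OS cells were grouped by their labels into DMSO, 75 µM apigenin and 75 µM luteolin at 24 h, with 2 libraries per group described as biological duplicates. Per the labels' protocols, total RNA was made into stranded mRNA libraries and sequenced on an Illumina NextSeq. Per the submitters' processing notes, STAR was used and hg38 was the genome build; versions and settings were not given in the sources used here.

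The authors' deposited tables, 10 in all, list splicing events of 5 types (skipped exon, retained intron, alternative 3' splice site, alternative 5' splice site, mutually exclusive exons) for apigenin against DMSO and luteolin against DMSO. Per the file headers, each cell of a count column packs the whole-number read counts of both libraries of a group, over the target and its junctions, for the inclusion and the skipping form. The values inside a cell carry no replicate number, so they are called value 1 and value 2. The tables also hold effective lengths of both forms, by which the authors divided counts, and the authors' p-value and false discovery rate for each event, per the file headers. Of the other per-sample columns, 20 in total with the authors' inclusion levels, none was used. The tables held 50403 skipped-exon events for apigenin and 44020 for luteolin, and 3667 and 3690 retained-intron events. Every skipped-exon and retained-intron event had at least 1 read of each form in some library, so exons never seen skipped were not analysed here.

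The inclusion level was computed as the length-normalised inclusion reads divided by the sum of both length-normalised forms. Recomputed differences lay within 0.0015 of the authors' for 100.0% of events, after turning their sign, since the tables give DMSO minus compound. Because counts packed in cells are not plain count columns, the test was limma 3.58.1 in R 4.3.3 on the log2 ratio of length-normalised inclusion to skipping reads, with a pseudocount of 0.5 reads, observation weights from the read counts and a constant prior variance. Events with a mean of at least 20 reads per library were tested. Adjusted p-values are Benjamini-Hochberg within event type, and an event was called at an adjusted p below 0.05 with a change of at least 10 percentage points. Each compound was tested in its own tables. The compounds were compared as a contrast in a fit of all 6 libraries over events whose coordinates and DMSO counts were identical in both tables, which held for 100.0% of shared events of 4 types and left out 48 of 3530 shared introns. The 4 or 6 libraries of a fit give few residual degrees of freedom, so p-values lean on the spread pooled over events. In every main apigenin fit, and for skipped exons and exclusive pairs with luteolin, the pooled spread replaced that of the event's own libraries entirely. Disagreement between the libraries of a group at an event therefore did not raise its p-value there.

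On data simulated from the real means, depths and overdispersion, unchanged data gave 9 calls among 32567 skipped-exon events for apigenin and 3 among 28618 for luteolin. Their unadjusted p fell under 0.05 in 9.15% and 8.34% of these events, above the nominal 5%, so unadjusted counts run high. Where changes were planted, 40 of 102 skipped-exon calls for apigenin and 19 of 72 for luteolin were false, above the 5% that the adjusted p allows. Of planted 2-fold changes, 19.4% were recovered for apigenin and 23.0% for luteolin, and of 4-fold changes 45.5% and 33.3%, among 32510 and 28677 events. For introns, 7.1% and 13.1% of 2-fold and 25.0% and 40.8% of 4-fold changes were recovered among 2557 and 2638 events. Few changes were planted, which made the adjusted p threshold stricter than in the real fits. They were also planted only in events of intermediate level, while many real calls started near full inclusion. These shares therefore do not measure what the real fits could detect or how many of their calls were false. The permutation test of medians gave p under 0.05 in 5.0% of 300 unshifted simulated sets of 1000 introns.

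Introns and exons were matched to GENCODE 29 transcripts on the same build, which annotated 96.0% of retained introns and 100.0% of skipped exons. Splice sites were scored in bits by a position weight matrix from 31879 annotated introns, over 3 exonic and 6 intronic bases at the 5' site and 20 intronic and 3 exonic bases at the 3' site. The 31879 introns were those whose splice sites lay inside an annotated exon of another transcript, since no genome sequence was at hand. Unchanged introns were themselves listed as retained-intron events, so scores compare such introns with one another. Sequence was at hand for 99.9% of retained introns. For skipped exons it covered 22.8% of 5' and 23.0% of 3' sites, so that check was void. Medians of changed targets were compared with unchanged ones (unadjusted p above 0.05 and a change under 5 points) by two-sided permutation tests with 100000 resamples, adjusted over 32 tests. Introns and exons are not independent replicates of the treatment, so these tests describe which targets changed in these libraries. Gene lists, 15 in all, were tested for more changed genes than 10000 random lists matched on the number of tested events and reads (one-sided, adjusted over the lists). Calls were also counted with p-values adjusted over the list alone. These gave with apigenin 3 SR protein, 13 hnRNP and PTB, 11 of 3' and 8 of 5' splice site recognition, 10 kinase, 9 detained intron, 8 decay, 7 export, 13 apoptosis, 22 cell cycle, 27 repair, 11 initiation factor and 11 ribosomal protein genes, and with luteolin 5, 11, 8, 5, 7, 10, 6, 2, 8, 7, 15, 5 and 8 in the same order, and 0 in the other lists. Shared calls were set beside 20 simulations of unchanged groups against the same DMSO libraries.

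The gene lists, the main tests and the rule for named genes were fixed before the data were examined. A prior variance as a trend on the weights, treated values beyond both DMSO values, left-out libraries with the spread from all groups, backgrounds matched on the inclusion level in DMSO, and a different DMSO library for each compound were chosen after results were seen. From called events with at least 50 reads per group and treated values beyond both DMSO values (a share of 33% by chance), 1 event per gene was taken by size of change. These were 4 skipped exons and 4 introns in each direction, 2 events of each alternative splice site type in each direction, 2 mutually exclusive pairs, up to 4 called members per list, and 4 skipped exons or introns in each direction between compounds. Some members that this rule takes are not reported here. Alternatives were no filter, a filter of 50 reads, a pseudocount of 1 read, no weights, a minimum change of 5 points, adjustment over all types, distinct targets, the authors' deposited FDR, 1 fit of all libraries, other backgrounds and site models, Fisher's exact test for lists, and each library left out in turn. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 was used. Confidence intervals of shares are Wilson 95% intervals, which cover counting error only, since reads had no molecular identifiers.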

Results

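Splicing was measured in U2OS cells, a human osteosarcoma line, by RNA sequencing of poly(A)-selected, strand-marked libraries. The 6 libraries fell into 3 groups of biological duplicates: cells given the solvent DMSO, cells given 75 µM apigenin and cells given 75 µM luteolin, all collected after 24 h. Apigenin and luteolin are plant flavones that differ by an extra hydroxyl group on the B ring of luteolin, which makes that ring a catechol. For each splicing event, reads of the form that contains the target sequence and of the form that lacks it gave an inclusion level (PSI, the percentage of transcripts with the target). Skipped-exon events drew 11224697 to 14416608 reads per library of the apigenin comparison, and retained-intron events 864017 to 1109497. The skipped-exon reads of the libraries of a group differed beyond counting noise, with a chi-square per degree of freedom of 2.14 to 3.29, so they were not copies of the same reads. Changes are given in percentage points with hg38 coordinates, and levels as mean ± SD (n = 2).

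The comparison of apigenin with DMSO asked which splicing events the compound changed. Apigenin lowered the inclusion of many exons and raised that of fewer. Among exons that rose, 2 genes for heterogeneous nuclear ribonucleoproteins (hnRNPs), which bind AU-rich RNA, led. An untranslated exon of HNRNPDL (ENSG00000152795, chromosome 4, 82425563 to 82425667) went from 12.0% ± 0.7 to 85.1% ± 1.7 (SD, n = 2). An untranslated exon of HNRNPD (chromosome 4, 82354895 to 82355001) went from 2.3% ± 0.0 to 74.0% ± 0.9. Among exons that fell, a coding exon of MAIP1, which encodes a mitochondrial matrix protein (chromosome 2, 199961781 to 199961928), went from 89.7% ± 5.0 to 14.4% ± 0.9. An exon of UBE2A, a ubiquitin-conjugating enzyme of DNA damage tolerance (chromosome X, 119581507 to 119581596), went from 95.6% ± 1.0 to 25.5% ± 8.6. A coding exon of the transcriptional coactivator gene PPRC1 dropped from 100% ± 0.0 to 28.6% ± 8.0, and an exon of BRMS1, a suppressor of metastasis, from 97.1% ± 4.1 to 28.9% ± 2.3. Exons of the nucleosome-binding gene HMGN1 (34.1% ± 15.5 to 100% ± 0.0) and of ACSF3, a mitochondrial acyl-CoA synthetase gene (32.8% ± 0.6 to 89.5% ± 4.2), also rose. A level of 100% ± 0.0 means only that no skipping read was seen in that group, and HMGN1 had an adjusted p of 0.011 (limma).

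Of 39754 skipped-exon events tested with apigenin, 628 were higher and 3190 lower (limma, adjusted p below 0.05 and a change of at least 10 points). The lowered events covered 2963 distinct exons in 1983 genes, and their median level went from 97.8% to 74.0%, a median change of -20.4 points. The raised events covered 597 exons in 499 genes, with a median change of 21.9 points. An exon at 95% or more in DMSO can move only down by 10 points, and 2030 of the lowered events were of that kind. Among exons at 20% to 80% in DMSO, 332 rose and 451 fell. An event needed a read of each form in some library to be listed, and 20718 listed events had skipping reads only in apigenin libraries, against 8778 only in DMSO. Skipping reads made up 5.98% ± 0.01 of the reads of skipped-exon events in DMSO and 6.52% ± 0.12 in apigenin.

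**Figure D1:**
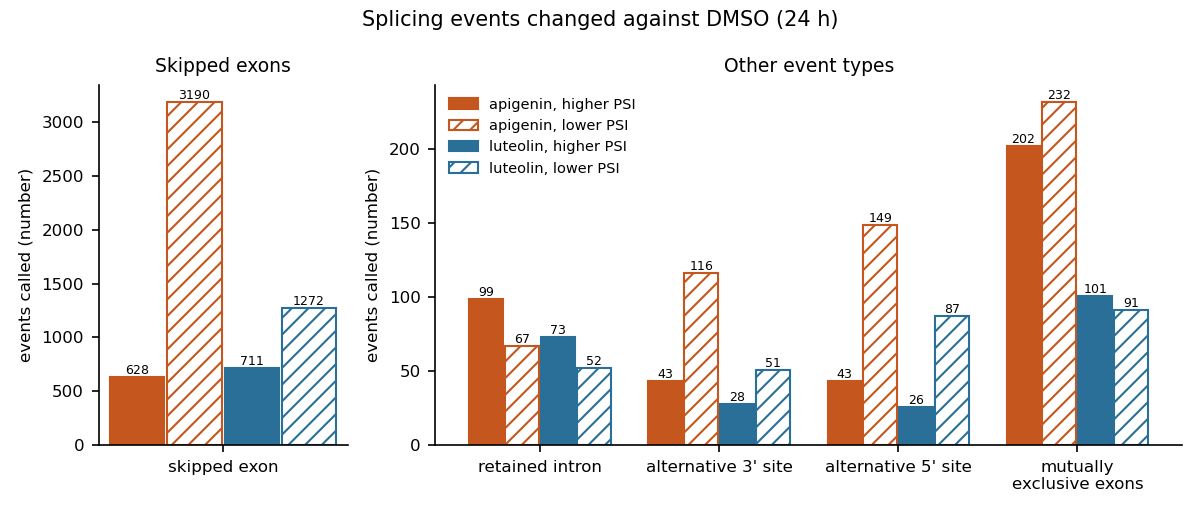
Number of splicing events called higher (filled bars) or lower (hatched bars) than in DMSO after apigenin or luteolin, by event type, with skipped exons on their own axis. Apigenin gave 3190 lowered and 628 raised skipped-exon events, and luteolin 1272 and 711.

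Introns moved in both directions with apigenin. An intron of OGT, the gene of O-GlcNAc transferase (chromosome X, 71544636 to 71547906), was retained in 13.6% ± 3.3 of transcripts in DMSO and 70.8% ± 8.8 with apigenin. Retention also rose in FNBP1L, a gene of membrane curvature and actin (28.5% ± 0.9 to 83.8% ± 10.0), in NDUFAF7, an assembly factor of respiratory complex I (15.8% ± 3.1 to 61.3% ± 23.7), and in METTL17, a mitochondrial ribosome factor (6.8% ± 3.8 to 48.5% ± 8.1). Retention fell for an intron of the ribosomal protein gene RPL23 (chromosome 17, 38850215 to 38852603), from 99.2% ± 1.1 to 15.8% ± 2.9. It also fell in ACAA1, a peroxisomal thiolase (79.6% ± 1.5 to 14.7% ± 1.8), in IDH3B, a subunit of isocitrate dehydrogenase (100% ± 0.0 to 42.0% ± 11.5), and in NSG1, a gene of endosomal sorting (100% ± 0.0 to 30.6% ± 1.7). In all, 99 of 2622 tested introns were retained more and 67 less. Without DMSO value 1 or 2 they numbered 69 and 44, and 84 and 29, and without apigenin value 1 or 2 they numbered 65 and 32, and 66 and 37. The authors' deposited table gave 137 more and 135 less, with no such imbalance. With no weights, limma called 0 introns, with 513 at an unadjusted p under 0.05. The library median of retention was 4.48% ± 0.56 in DMSO and 5.43% ± 0.03 in apigenin, a difference of 0.95 points with an exact permutation p of 0.33 (two-sided), the smallest that 2 libraries against 2 can give.

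Alternative splice sites mostly moved toward the shorter exon with apigenin. Of 3267 events with alternative 3' splice sites, 43 were higher and 116 lower, and of 2131 with alternative 5' splice sites, 43 were higher and 149 lower. The 5' splice site extension of UBL5, a ubiquitin-like splicing factor, fell from 92.0% ± 4.5 to 14.3% ± 0.9, and that of ACAA1 from 91.3% ± 1.3 to 28.4% ± 1.4. The ACAA1 extension lies inside the ACAA1 intron above, so these may not be separate changes. Extensions of PDCD6, a calcium-binding protein gene (38.7% ± 9.8 to 100% ± 0.0), and of REPS1, a gene of endocytosis (8.4% ± 5.3 to 52.2% ± 8.7), rose. At 3' splice sites, ZNF655, a zinc finger gene, rose from 46.6% ± 10.3 to 90.6% ± 5.6 and SUPT20H, a SAGA complex gene, from 10.3% ± 2.8 to 45.3% ± 23.5. STK19, a gene of transcription-coupled repair, fell from 82.4% ± 24.9 to 14.5% ± 0.2, and TROAP, a gene of spindle assembly, from 100% ± 0.0 to 44.0% ± 2.4. Without DMSO value 1 or 2, or apigenin value 1 or 2, the 159 changed 3' events became 83, 81, 0 and 0 by limma, with 409 and 421 at an unadjusted p under 0.05 in the last fits. The 192 changed 5' events became 115, 112, 0 and 0, with 396 and 418. Of 8752 pairs of mutually exclusive exons, 202 were higher and 232 lower (281, 242, 127 and 154 changed in the same order of left-out libraries). They were led by MATR3, a nuclear matrix gene (1.7% ± 0.9 to 54.9% ± 12.0), and ARIH2, a ubiquitin ligase gene (4.0% ± 2.2 to 50.8% ± 3.6).

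Lists of splicing genes were compared with matched random lists after apigenin, and none passed an adjusted p of 0.05. Of 23 measured hnRNP and PTB genes, 13 had a changed event, where random lists matched on events and reads averaged 7.5 (adjusted p = 0.064). Among them were exons of HNRNPUL1 (95.9% ± 0.8 to 31.6% ± 2.5) and HNRNPH1 (89.1% ± 3.8 to 53.6% ± 5.5). Of 15 SR protein kinases and relatives, 10 changed against 5.9 (adjusted p = 0.064). They included a 5' extension of CLK3 (50.4% ± 7.4 to 94.1% ± 8.4), an intron of PRPF4B (75.1% ± 11.5 to 41.1% ± 4.8) and exons of SRPK2 (89.6% ± 8.9 to 63.9% ± 11.8) and CDK11B (90.6% ± 0.6 to 68.2% ± 3.7). Of 21 genes of 3' splice site recognition, 10 changed against 7.4 (adjusted p = 0.34). Exons of SNRPA1 (96.3% ± 1.5 to 41.3% ± 13.6) and SF3A3 (95.3% ± 6.7 to 48.7% ± 12.2) fell, retention of an SF1 intron fell (75.3% ± 1.3 to 43.6% ± 5.6) and that of an SF3B1 intron rose (39.4% ± 13.7 to 80.9% ± 14.5). Of 12 genes of 5' splice site recognition, 7 changed against 5.0 (adjusted p = 0.38), with PRPF39 and TIAL1 lower and an intron of RBM25 higher (9.6% ± 2.8 to 33.8% ± 0.2). Of 12 SR protein genes, 3 changed against 2.9 (adjusted p = 0.83). These were exons of SRSF1 (95.7% ± 1.8 to 66.2% ± 3.2) and TRA2A (0.6% ± 0.5 to 26.7% ± 13.4) and a 3' extension of SRSF5 (chromosome 14, 69768798 to 69769181, 100% ± 0.0 to 84.8% ± 2.8). Of 13 genes known for introns that stay in nuclear RNA (detained introns), 9 changed against 5.9 (adjusted p = 0.14). Among them was DDX5, an RNA helicase gene, with an intron that rose from 7.6% ± 1.4 to 28.6% ± 4.4. Lists counted exons and splice sites as well as introns. Of the detained intron genes 5 had a raised exon, 6 a lowered exon, 3 an intron retained more and 0 one retained less. No changed event was found in 8 minor spliceosome genes (0 of 8, limma).

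Genes of cell division, cell death and DNA repair also carried changed events with apigenin, mostly exons that fell. Of 42 cell cycle and mitosis genes, 21 changed against 13.5 in matched lists (adjusted p = 0.064). Exons fell in the cohesin genes SMC1A (97.9% ± 0.1 to 48.2% ± 0.9) and NIPBL (100% ± 0.0 to 64.3% ± 1.1) and in SGO1, which protects cohesin (51.3% ± 7.8 to 11.8% ± 0.5). A 3' extension rose in the cyclin gene CCNL2 (55.7% ± 3.5 to 80.2% ± 4.5). The CCNL2 extension spans an intron whose retention moved the other way, by -39.0 points to 57.5% ± 9.8, without a call (limma, adjusted p = 0.0555). Of 25 apoptosis and p53 genes, 13 changed against 7.7 (adjusted p = 0.064). Exons fell in XIAP, an inhibitor of caspases (53.6% ± 13.9 to 17.7% ± 3.4), its antagonist DIABLO (90.9% ± 0.5 to 62.3% ± 2.2), CASP8 (100% ± 0.0 to 74.8% ± 1.7) and BAX (95.3% ± 2.3 to 74.9% ± 2.1). Of 53 DNA repair genes, 25 changed against 22.8 (adjusted p = 0.49), including exons of FANCI (100% ± 0.0 to 65.4% ± 4.3), ERCC6 (100% ± 0.0 to 64.8% ± 0.9), LIG3 (97% ± 4.3 to 64.6% ± 6.3) and TP53BP1 (100% ± 0.0 to 68.3% ± 5.3). Of 38 translation initiation factors, 11 changed (adjusted p = 1.0), including a 5' extension of EIF4G2 (61.2% ± 2.1 to 23.5% ± 3.3) and an exon of EIF4A2 (78.1% ± 0.2 to 47.1% ± 11). Of 79 ribosomal protein genes, 11 changed (adjusted p = 1.0), with an RPL5 exon (chromosome 1, 92833389 to 92833458) lower (99.6% ± 0.1 to 59.9% ± 4.3) and an RPS24 exon higher (16.1% ± 2.0 to 40.3% ± 2.2). Of 17 genes of nonsense-mediated decay and the exon junction, 8 changed (adjusted p = 0.39), including MAGOH (79.4% ± 0.9 to 55.9% ± 4.3) and MAGOHB (2.3% ± 0.6 to 22.3% ± 5.8). Of 16 mRNA export genes, 7 changed (adjusted p = 0.71), including THOC1 (99.3% ± 1.0 to 63.6% ± 2.1). Of 2 measured markers of other cell types, 0 changed.

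**Figure D2:**
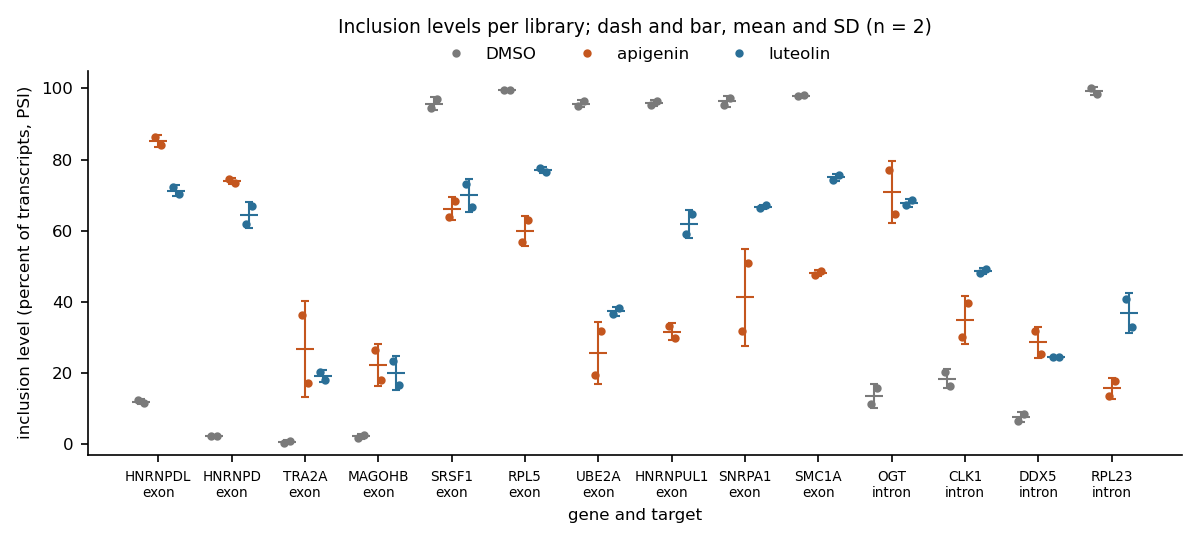
Inclusion level (percent) of 10 exons and 4 introns in each of the 6 libraries, with a dot per library and the mean and SD (n = 2) as a dash and bar. HNRNPDL rose from 12.0% in DMSO to 85.1% with apigenin and 71.2% with luteolin, and RPL5 fell from 99.6% to 59.9% and 77.0%.

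The series addresses introns with weak splice sites, so features of changed targets were compared with unchanged ones. Unchanged introns were also listed as retained-intron events, so introns in general were not compared. Inclusion reads were counted over the target, so a longer intron can collect more reads and be called more easily. A difference in length is therefore not by itself a trait of the response. Introns retained more with apigenin were longer (median 316 bp against 205 bp, permutation test, adjusted p = 0.0057), and weaker splice sites were not shown for them. Their 5' splice site score was 7.84 bits against 7.64 (adjusted p = 0.80) and their 3' score 9.04 against 8.61 (adjusted p = 0.33). Introns retained less were also longer (348 bp against 205 bp, adjusted p = 0.0057), with a 5' score of 6.87 against 7.64 (adjusted p = 0.13) and a 3' score of 8.31 against 8.61 (adjusted p = 0.67). The latter length difference was lost against introns of like retention in DMSO (348 bp against 303 bp, adjusted p = 0.57). With 1 library left out that difference was 134 to 148 bp, but its call was lost in 3 of 4 fits. Exons that fell had less GC (46.4% against 48.3%, adjusted p = 6.4e-05) and exons that rose more (53.9% against 48.3%, adjusted p = 6.4e-05), both from 1e-05, the smallest p the permutations could give. Splice site scores of skipped exons were void, because sequence was at hand for 22.8% of 5' and 23.0% of 3' sites.

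In limma fits, skipped-exon calls with apigenin fell from 3818 to 1900 without DMSO value 1, to 1905 without DMSO value 2, and to 0 without apigenin value 1 or 2 (13152 and 13791 at an unadjusted p under 0.05), where 84.8% and 91.8% of the calls kept their direction and 10 points and the spread from all groups gave 2706 and 3217 calls (161 and 127 without DMSO value 1 or 2), and no weights gave 244 higher and 1890 lower. Simulated unchanged events at the same p threshold amounted to 11.5% of these calls, and the authors' deposited table gave 3758 at an FDR under 0.05 and the same minimum change.

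The comparison of luteolin with DMSO asked the same question for the catechol flavone. Luteolin raised the exons of HNRNPD, from 2.3% ± 0.0 to 64.4% ± 3.6, and HNRNPDL, from 12.0% ± 0.7 to 71.2% ± 1.5 (SD, n = 2). It raised an exon of the chromatin remodelling gene SS18 (chromosome 18, 26035831 to 26035923) from 29.3% ± 9.7 to 81.9% ± 6.0 and an exon of HMGN1 from 34.1% ± 15.5 to 100% ± 0.0. It lowered exons of MAIP1 (89.7% ± 5.0 to 26.7% ± 0.6), UBE2A (95.6% ± 1.0 to 37.4% ± 1.2), BRMS1 (97.1% ± 4.1 to 41.3% ± 14.1) and FAM126A, a gene of phosphoinositide synthesis (77.7% ± 0.2 to 19% ± 1.9). Of 34827 skipped-exon events tested, 711 were higher, with a median change of 20.3 points, and 1272 lower, with a median change of -19.3 points. Among exons at 20% to 80% in DMSO, 408 rose and 311 fell, and 592 of the lowered events were at 95% or more in DMSO. Skipping reads were seen only in luteolin libraries in 14441 listed events, and only in DMSO in 9049. Skipping reads made up 6.52% ± 0.00 of the reads of skipped-exon events in DMSO and 6.55% ± 0.01 in luteolin, over the events of the luteolin comparison.

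An intron of CEP192, a centrosome gene (chromosome 18, 13057734 to 13059081), was retained more with luteolin, at 68.2% ± 13.6 from 6.2% ± 0.5. Retention also rose in OGT (13.6% ± 3.3 to 67.9% ± 1.0), FNBP1L (28.5% ± 0.9 to 66.9% ± 9.2) and NDUFAF7 (15.8% ± 3.1 to 53.1% ± 7.2). Retention fell in RPL23 (99.2% ± 1.1 to 36.9% ± 5.5), in TMEM41B, a lipid scramblase gene (96.9% ± 4.5 to 40.1% ± 4.6), in the amino acid transporter gene SLC7A6 (93.8% ± 8.7 to 37.3% ± 6.2) and in TAF15, an RNA-binding protein gene (94.1% ± 8.3 to 41.9% ± 0.6). In all, 73 of 2707 tested introns were retained more and 52 less. These 125 calls became 60 without DMSO value 1, 64 without DMSO value 2, 19 without luteolin value 1 and 55 without luteolin value 2. With no weights limma called 0, with 476 at an unadjusted p under 0.05, and the authors' deposited table gave 111 and 110. The library median was 4.50% ± 0.55 in DMSO and 5.33% ± 0.09 in luteolin, a difference of 0.83 points with an exact permutation p of 0.33 (two-sided), again the smallest possible.

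At alternative splice sites luteolin gave 28 higher and 51 lower among 3328 3' events, and 26 higher and 87 lower among 2163 5' events. ZNF655 (46.6% ± 10.3 to 89.5% ± 7.1) and the transcription factor gene TCF3 (57.2% ± 5.8 to 93.5% ± 0.4) rose at 3' sites, and STK19 (82.4% ± 24.9 to 23.5% ± 4.7) and PLD3, a lysosomal nuclease gene (85.0% ± 10.4 to 37.7% ± 9.3), fell. PDCD6 (38.7% ± 9.8 to 100% ± 0.0) and CLK3 (50.4% ± 7.4 to 96.4% ± 5.1) rose at 5' sites, and UBL5 (92.0% ± 4.5 to 29.9% ± 5.1) and XPNPEP1, an aminopeptidase gene (75.8% ± 8.1 to 29.8% ± 1.1), fell. Without any 1 of the 4 libraries limma called 0 events of either kind, with 268 to 329 at an unadjusted p under 0.05 at 3' sites and 236 to 320 at 5' sites. Of 6924 pairs of mutually exclusive exons, 101 were higher and 91 lower (137 and 125 changed without DMSO value 1 or 2, 47 and 56 without luteolin value 1 or 2). They were led by the phosphatase gene ACP1 (79.8% ± 4.3 to 39.2% ± 1.9) and the growth factor gene NRG1 (25.5% ± 4.5 to 63.5% ± 2.4).

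Among the fixed lists, 2 stood above matched random lists with luteolin. Of 13 genes with known detained introns, 9 changed against 3.6 (adjusted p = 0.021). Of these genes 7 had a raised exon, 1 a lowered exon, 4 an intron retained more and 0 one retained less. The call therefore rested on more than introns. A CLK1 intron (chromosome 2, 200859747 to 200861237), in a kinase gene for SR proteins, rose from 18.4% ± 2.7 to 48.7% ± 0.7, and a TRA2A exon rose from 0.6% ± 0.5 to 19.2% ± 1.7. The adjusted p was 0.14 with a minimum change of 5 points and 0.051 without luteolin value 1. Of 23 hnRNP and PTB genes, 11 changed against 5.4 (adjusted p = 0.040), with exons of HNRNPH1 at 53.3% ± 10.7 (from 89.1% ± 3.8) and HNRNPUL1 at 61.9% ± 4.0 (from 95.9% ± 0.8). The adjusted p was 0.14 with the FDR of the authors' deposited table, 0.67 and 0.16 without DMSO value 1 or 2, and 0.83 and 0.84 without luteolin value 1 or 2, where introns were the only limma calls that the lists count, so a list carried by exons could not keep its call. Of 12 SR protein genes, 5 changed against 2.3 (adjusted p = 0.11). They included an exon of SRSF1 (95.7% ± 1.8 to 69.9% ± 4.6), a 3' extension of SRSF5 (chromosome 14, 69769511 to 69770466, 12.9% ± 3.2 to 26.0% ± 3.3) and an exon of SRSF7 (4.8% ± 0.2 to 15.1% ± 1.2). The SRSF5 extension named with apigenin is a different one, which changed by -4.3 points with luteolin without a call. Of 21 genes of 3' splice site recognition, 8 changed against 3.8 (adjusted p = 0.087). They included a 3' extension of SF1 (84.8% ± 0.8 to 47.3% ± 4.5), exons of SNRPA1 (96.3% ± 1.5 to 66.7% ± 0.6) and SF3A3 (95.3% ± 6.7 to 65.9% ± 5.1) and an intron of SF3B1 (39.4% ± 13.7 to 68.2% ± 7.8). The SF1 extension spans the SF1 intron named with apigenin. Of 12 genes of 5' splice site recognition, 5 changed against 2.6 (adjusted p = 0.20), including 5' extensions of TIA1 (14.2% ± 3.3 to 43.1% ± 2.0) and SNRNP70 (50.4% ± 11.8 to 85.6% ± 1.9). Of 15 SR protein kinases and relatives, 7 changed against 3.4 (adjusted p = 0.10), with a raised event in 6 genes, such as the CLK1 intron above and the CLK3 5' extension, and a lowered event in 2, which were exons of SRPK2 (89.6% ± 8.9 to 65.6% ± 8.6) and HIPK3 (100% ± 0.0 to 82.8% ± 6.7).

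The remaining lists did not stand apart with luteolin. Changed events were found in 6 of 17 genes of nonsense-mediated decay and the exon junction (adjusted p = 0.20), such as RNPS1 (54.8% ± 3.7 to 70.9% ± 3.2). They were also found in 2 of 15 mRNA export genes (adjusted p = 1.0), which were ZC3H11A (55.4% ± 3.0 to 90.9% ± 3.2) and DDX39B (54.2% ± 4.3 to 40.4% ± 2.9). Of 24 apoptosis and p53 genes, 6 changed (adjusted p = 0.44). Exons of BID (43.0% ± 4.5 to 77.8% ± 0.7) and BBC3 (88.0% ± 5.8 to 98.7% ± 1.8) rose, and that of BAX (95.3% ± 2.3 to 79.2% ± 0.6) fell. Of 42 cell cycle and mitosis genes, 7 changed (adjusted p = 1.0), with SMC1A at 75.0% ± 1.1 (from 97.9% ± 0.1) and SGO1 at 27.8% ± 0.3 (from 51.3% ± 7.8). Of 54 DNA repair genes, 16 changed (adjusted p = 0.66), including MDC1 (75.0% ± 0.7 to 21.3% ± 6.6) and LIG1 (94.2% ± 0.6 to 72.3% ± 1.1). Changes were also found in 5 of 38 translation initiation factors (adjusted p = 1.0), such as EIF4E (0.8% ± 0.2 to 11.6% ± 0.8). Of 76 ribosomal protein genes, 8 changed (adjusted p = 1.0), such as an exon of RPL17 (15.2% ± 2.9 to 39.9% ± 2.4) and an intron of RPS9 (37.2% ± 3.9 to 15.2% ± 1.4). No change was called in 8 minor spliceosome genes or in 2 markers of other cell types.

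Introns retained more with luteolin were longer than unchanged introns (483 bp against 207 bp, adjusted p = 6.4e-05). Weaker splice sites were not shown for them, with a 5' score of 8.22 bits against 7.58 (adjusted p = 0.20) and a 3' score of 8.89 against 8.60 (adjusted p = 0.67). Introns retained less had a median length of 296 bp against 207 bp (permutation test, adjusted p = 0.085). The limit on length given with apigenin applies to both sets. Introns retained less had lower 5' scores (6.40 against 7.58, adjusted p = 0.033). That call did not hold with a first-order Markov model of the site, where the difference was -0.54, with the authors' deposited table (-0.50), against introns of like retention in DMSO (-1.06), or with 1 library left out (-1.38 to -0.07). Exons that fell had less GC (45.8% against 47.9%, adjusted p = 0.00011), and exons that rose had more GC (54.8% against 47.9%) and were longer (129 bp against 116 bp), each with an adjusted p of 6.4e-05 from the smallest p of 1e-05.

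**Figure D3:**
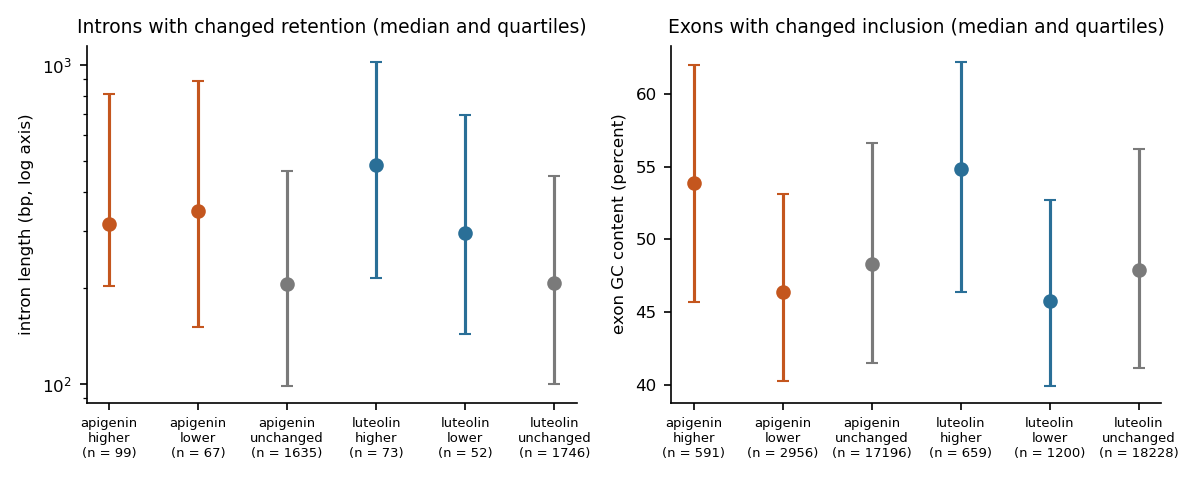
Median and quartiles of intron length (bp, log axis) for introns retained more, retained less or unchanged, and of exon GC content (percent) for exons raised, lowered or unchanged, by compound. Introns retained more had medians of 316 bp with apigenin and 483 bp with luteolin, against 205 bp and 207 bp in unchanged introns.

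In limma fits, 0 skipped-exon events were called with luteolin without DMSO value 1 or 2 or luteolin value 1 or 2, where 3717, 3554, 7672 and 7617 had an unadjusted p under 0.05, 89.5% to 93.3% of the calls kept their direction and 10 points, and the spread from all groups gave 21, 19, 1291 and 1378 calls, and no weights gave 34 higher and 119 lower. Simulated unchanged events at the same p threshold amounted to 11.8% of the skipped-exon calls, and the authors' deposited table gave 1897.

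The flavones were compared directly at the same dose and time, over events found in both tables, to ask whether the extra hydroxyl group went with a different response. Exons were included more with luteolin than with apigenin far more often than less. Of 28003 skipped-exon events, 862 were higher and 45 lower in luteolin (limma, adjusted p below 0.05 and at least 10 points), with a median difference of 17.4 points among the former. ST6GALNAC4, a sialyltransferase gene (chromosome 9, 127909951 to 127910528), stood at 93.8% ± 8.8 with luteolin and 35.1% ± 1.5 with apigenin (SD, n = 2). ZKSCAN8, a zinc finger gene, stood at 95.8% ± 5.9 and 44.1% ± 14.7, FIP1L1, a polyadenylation factor gene, at 87.4% ± 1.4 and 39.7% ± 4.4, and RPRD1B, a regulator of RNA polymerase II, at 96.2% ± 5.4 and 56.7% ± 6.9. Lower in luteolin were exons of UBE2G2, a ubiquitin-conjugating enzyme gene (18.6% ± 0.2 against 52.7% ± 10.0), of the kinase gene MAP4K3 (40% ± 9.2 against 66.4% ± 7.1) and of SF1 (43.8% ± 2.2 against 66.3% ± 3.3), and an intron of the kinase gene ABL2 (14.8% ± 4.8 against 37.1% ± 11.5). The SF1 exon lies within the SF1 extension named with luteolin. HNRNPDL was 13.9 points lower with luteolin (adjusted p = 5.85e-05), and HNRNPUL1 was higher by 30.3 points (adjusted p = 2.48e-06), SMC1A by 26.8 (adjusted p = 0.000297) and RPL5 by 17.1 (adjusted p = 9.08e-23).

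For many single exons and introns no difference between the flavones was shown, but wide intervals leave differences open. SRSF1 differed by 0.24 on the log2 scale of the inclusion to skipping ratio (95% interval -0.10 to 0.58, adjusted p = 0.532), HNRNPH1 by -0.12 (interval -0.52 to 0.29, adjusted p = 0.906) and the OGT intron by -0.04 (interval -0.84 to 0.76, adjusted p = 0.989). Of 3757 skipped-exon events called with either compound, the difference missed an adjusted p of 0.05 in 2730, whose 95% intervals reached a median of 1.02 log2 units to either side. The median difference of these 2730 was 0.62 log2 units toward luteolin. The 3757 events were picked by calls in the same libraries, mostly as lowered with apigenin, which by itself pulls the difference toward luteolin. That median therefore does not show whether such exons as a set differed between the flavones. Of 197 introns called with either compound, 173 missed that adjusted p. Their intervals reached a median of 0.90 to either side, and their median difference was -0.05. Among 2574 introns, 4 were higher and 15 lower in luteolin (10 called without DMSO value 1 or 2, 9 without luteolin value 1, 12 without luteolin value 2). Among 3099 events with alternative 3' sites 13 were called, all higher (1 without DMSO value 1 or 2, 2 without apigenin value 1 or luteolin value 1). Among 2009 with alternative 5' sites 9 were higher and 1 lower (0 by limma without DMSO value 1 or 2, with 164 at an unadjusted p under 0.05, and 15 without luteolin value 2). Among 4916 mutually exclusive pairs 20 were higher and 9 lower (14 called without apigenin value 1 and 15 without luteolin value 1). Skipped-exon calls numbered 907, and by limma 0 without DMSO value 1 or 2 (3530 and 3528 at an unadjusted p under 0.05) and 514 without luteolin value 1. With no weights limma called 0 events of any type, with 2496 skipped exons at an unadjusted p under 0.05.

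**Figure D4:**
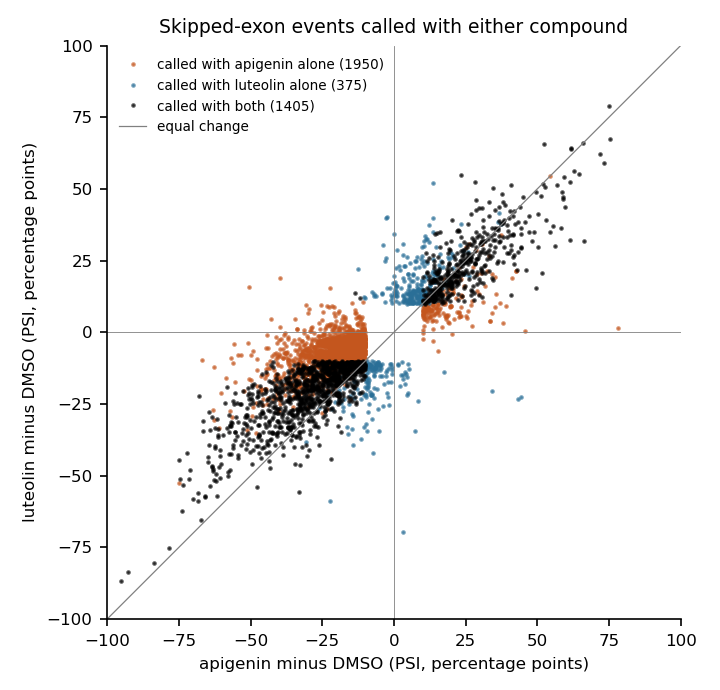
Change in inclusion level (percentage points against DMSO) with luteolin on the vertical axis and apigenin on the horizontal axis, with a point per skipped-exon event called with either compound and a line of equal change. Of 3730 events, 1405 were called with both, and the points that fell with apigenin lie mostly above the line of equal change.

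Exons that one flavone changed mostly moved the same way with the other. Among 27579 skipped-exon events tested in both comparisons, 420 were higher and 983 lower with both compounds and 2 went opposite ways, where independent lists would share 13.6 and 114.3. Of 1137 exons lowered by luteolin, 983 (86.5%, Wilson 95% interval 84.3% to 88.3%) were also called lower with apigenin. Of 2772 lowered by apigenin, 983 (35.5%, interval 33.7% to 37.3%) were called with luteolin, and the median change of these 2772 was -20.6 points with apigenin and -9.1 with luteolin. The 1137 lowered by luteolin changed by a median of -19.1 points with luteolin and -25.7 with apigenin. For introns, 54 were retained more and 34 less with both, against 2.8 and 1.4 for independent lists. Unchanged groups simulated against the same DMSO libraries made 0 calls at all in 20 simulations by the same limma fit, so their shared count of 0 sets no level for the overlap. The covariance of skipped-exon changes was 65.9 against 12.5 simulated (introns, 98.4 against 24.4). With a different DMSO library for each compound, which leaves no control in common, the covariance of skipped-exon changes was 56.6 and 56.7 in the 2 possible pairings (introns, 81.2 and 79.7). In these pairings 27 and 31 introns were retained more and 13 and 13 less with both compounds, against 1.2 and 1.3 and 0.2 and 0.3 for independent lists. Part of the covariance may thus come from the shared controls, and most of it remained without them.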

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

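METTL26 was looked at only after its values were seen. An exon of METTL26 (chromosome 16, 634889 to 635063) moved in opposite directions with the compounds, from 71.6% ± 5.2 in DMSO to 57.9% ± 6.9 with apigenin and 85.4% ± 0.7 with luteolin (SD, n = 2), a difference of 27.5 points (limma, adjusted p = 0.000275). An overlapping exon that ends at 634956 did the same, from 77.2% ± 5.3 to 65.3% ± 7.7 and 89.3% ± 1.3, a difference of 24.0 points (adjusted p = 0.000302). They were the 2 events called in opposite directions among 27579 skipped-exon events tested with both compounds. With the FDR of the authors' deposited table, or with the prior variance as a trend on the weights (chosen after results were seen), 0 events were called in opposite directions.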

How the results depend on the processing

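No paired analysis was possible because the values packed in a cell carry no replicate number, so no replicate block was fitted. The prior variance as a trend, the left-out libraries with the spread from all groups, the match on the level in DMSO and the different DMSO library for each compound were chosen only after results were seen.

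With no weights limma gave 244 higher and 1890 lower skipped exons for apigenin, with 0 introns in either direction (513 at an unadjusted p under 0.05), 5 events at 3' sites, 6 at 5' sites and 20 exclusive pairs. For luteolin it gave 34 and 119 skipped exons, with 0 introns (476 at an unadjusted p under 0.05), 0 events at 3' sites (413), 0 at 5' sites (353) and 0 pairs (814). Between compounds it gave 0 skipped exons (2496), 0 introns (191), 0 events at 3' sites (199), 0 at 5' sites (146) and 0 pairs (421). With 50 reads or more, apigenin raised 402 exons and 65 introns, and with no filter luteolin changed 45 events at 3' sites. Between compounds, a trend of the prior variance gave 454 higher and 15 lower exons and 7 events at 3' sites, and a pseudocount of 1 read gave 1 event at 3' sites. Adjustment over all types gave 7 higher introns, 21 events at 3' sites and 49 pairs. A minimum of 5 points gave 8 higher and 24 lower introns, 22 events at 3' sites, 20 at 5' sites and 51 pairs. The FDR of the authors' deposited table gave 135 introns lower with apigenin, 111 higher and 110 lower with luteolin, 123 luteolin events at 3' sites, and 72 introns lower with both. With a different DMSO library for each compound, 27 introns were higher and 13 lower with both when apigenin was set against value 1, and 31 and 13 when it was set against value 2. Counts of shared skipped exons gave no value there, since these fits called no luteolin exon against a single DMSO library.

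For the lists, Fisher's exact test over genes gave with apigenin an adjusted p of 0.02 for hnRNP, kinase, detained intron, cell cycle and DNA repair genes and 0.04 for apoptosis genes, and with luteolin 0.049 for kinases. A minimum of 5 points gave an adjusted p of 0.031 for apigenin cell cycle genes, 0.022 for luteolin SR proteins and 0.14 for luteolin detained introns, and the FDR of the authors' deposited table gave 0.14 for luteolin hnRNP genes.

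Differences of medians from unchanged targets also moved. With the authors' deposited table they were, for apigenin, -4.1 in GC and -0.17 in 5' score of introns retained more, -0.68 in 5' and -0.70 in 3' score of those retained less, and 4.0 bp and 10.0 bp in length of lowered and raised exons. For luteolin they were 81.5 bp in length, -0.50 in 5' and -0.86 in 3' score of introns retained less, 374 bp in the upstream intron of lowered exons and 88.5 bp in the downstream intron of raised exons. With unchanged targets matched on reads they were, for apigenin, 4.0 bp in length and -108 bp in downstream intron of lowered exons, and 11 bp and -19.0 bp for raised exons. For luteolin they were -4.7 in GC of introns retained more, 106 bp in length of introns retained less and -85.5 bp in downstream intron of lowered exons. Matched on the level in DMSO they were, for apigenin introns retained less, 45.0 bp, -4.1 in GC and 0.16 in 3' score, with -1.0 bp in length of lowered exons and 362 bp in upstream intron of raised exons. For luteolin introns retained less they were -56.0 bp, 2.7 in GC, -1.06 in 5' and 0.76 in 3' score, with -6.0 bp in length and -169 bp in downstream intron of lowered exons and 301 bp in upstream intron of raised exons. A Markov model of the site gave -0.05 in 5' and -0.08 in 3' score for apigenin introns retained more, -0.15 in 3' score for luteolin introns retained more and -0.54 in 5' score for those retained less.

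Each library was left out in turn in limma, which takes the lone library of a group to vary like the others, and again with the spread from all groups. Apigenin skipped exons ranged from 0 to 493 higher and 0 to 2761 lower, introns from 57 to 84 higher and 20 to 53 lower, 3' events from 0 to 113, 5' events from 0 to 125 and pairs from 127 to 281. Luteolin skipped exons ranged from 0 to 474 higher and 0 to 904 lower, introns from 10 to 67 higher and 9 to 45 lower, 3' events from 0 to 71, 5' events from 0 to 112 and pairs from 47 to 137. Between compounds, exons ranged from 0 to 1094 higher and 0 to 58 lower, introns from 1 to 5 higher and 7 to 16 lower, 3' events from 1 to 18, 5' events from 0 to 15 and pairs from 14 to 34. The overlap was counted in the fits of the remaining libraries alone, where exons called with both compounds could only be 0, since each left-out library left a comparison without skipped-exon calls, and introns ranged from 10 to 43 higher and 8 to 27 lower. The adjusted p of luteolin lists, tested in those same fits, where introns were the only calls that the lists count, ranged from 0.16 to 0.84 for hnRNP genes and 0.0015 to 0.051 for detained introns. For apigenin introns retained more, differences ranged from -7.1 to -5.1 in GC, -0.43 to 0.17 in 5' and -0.31 to 0.47 in 3' score. For those retained less they ranged from 134 to 148 bp in length, -6.5 to -2.6 in GC, -1.39 to -0.73 in 5' and -0.33 to 0.41 in 3' score. Apigenin lowered exons ranged from -2.5 to -2.0 bp in length and -88.5 to -59.5 bp in downstream intron, and raised exons from -261 to 48.0 bp in upstream and -137 to 174 bp in downstream intron. For luteolin introns retained more they ranged from -16.6 to -11.2 in GC, -0.05 to 0.47 in 5' and -0.39 to -0.30 in 3' score, and for those retained less from -6.3 to 3.8 in GC, -1.38 to -0.07 in 5' and -0.61 to 0.10 in 3' score.

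Of 147 named events, 37 stayed called with no weights, 145 with a pseudocount of 1 read and 139 with no filter. With 1 library left out, from 11 of 76 (without luteolin value 1) to 63 of 147 (without DMSO value 1) stayed called by limma on the remaining libraries. With the spread from all groups 61 of 69 did without apigenin value 1 or 2, 54 of 67 without luteolin value 1 or 2, and 45 and 44 of 136 without DMSO value 1 or 2. None turned direction, but this is no sign of stability. Events named against DMSO were taken with treated values beyond both DMSO values, so leaving out 1 library could not reverse them. With this depth and 2 libraries per group, many small changes may not have been detectable.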

Other observations

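Chosen only after results were seen were the genes with the most lowered exons, the share of lowered exons and the library medians among those at 20% to 80% in DMSO, and the matching of unchanged targets on their level in DMSO.

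With apigenin 29 genes had at least 5 distinct lowered exons and 1346 had 1, without regard to how many exons of a gene were tested. The most were 8 in YY1AP1, a gene of an INO80-associated coactivator, 7 in FANCI, a gene of crosslink repair, 7 in the sugar kinase gene NAGK and 6 in the ubiquitin ligase gene ARIH2. With luteolin 6 genes had at least 5, with 7 in FDPS, a gene of isoprenoid synthesis, 6 in ZBTB8OS, a gene of tRNA ligation, 5 in APTX, a gene of single-strand break repair, and 5 in C9orf84. Changed events of the skipped-exon, intron and alternative site types were found in 2545 of 8555 measured genes (29.7%) with apigenin and in 1527 of 8526 (17.9%) with luteolin.

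Exons raised by either flavone often lay outside coding sequence, as in HNRNPDL, HNRNPD and TRA2A. With apigenin 22.5% of 591 raised exons did so against 6.0% of unchanged exons (Fisher's exact p = 2.8e-38, two-sided), and with luteolin 23.4% of 659 against 6.3% (p = 2.6e-43). Unchanged exons are mostly near full inclusion, and against unchanged exons of like level in DMSO the shares were 22.5% against 17.8% (Fisher's exact p = 0.13) and 23.4% against 20.8% (Fisher's exact p = 0.47). The inclusion level in DMSO therefore could account for most of the difference, and these counts do not separate it from a preference for untranslated exons.

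A difference in the share of exons with a length of whole codons was not shown for apigenin. It was 41.9% of 2957 lowered exons against 40.6% of unchanged ones (Fisher's exact p = 0.19, two-sided). Coding and untranslated exons were counted alike, so this is not the share whose loss keeps a reading frame. With luteolin the shares were 44.9% of 1201 against 40.2% (Fisher's exact p = 0.0016), but against unchanged exons of like level in DMSO they were 44.9% and 44.8% (p = 1.0), so the level in DMSO remains open as the source.

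Apigenin lowered 3190 skipped-exon events and raised 628. An exon near full inclusion can only fall, which could give such an excess by itself. Among called exons at 20% to 80% in DMSO the excess was smaller, with 57.6% lower (Wilson 95% interval 54.1% to 61.0%). Levels within that range were not matched, and an exon high in it has more room to fall. Whether the ceiling accounts for much or all of the excess is therefore undecided. A test planned on exons with a mean of 20% to 80% over all libraries gave 76.2% lower, but that range also takes in exons that fell from near 100%, so it decides nothing. Thin coverage is unlikely as the source, since 87.9% were lower among called exons with at least 200 reads per library. Medians of the apigenin libraries over the same range of means, -12.09 and -13.83 points, decide nothing about library depth for the same reason, and over exons at 20% to 80% in DMSO they were -0.95 (95% interval -2.22 to 0.58) and -1.61 (-3.03 to -0.27). Library depth and, for part of the excess, the ceiling therefore stay open beside an effect of apigenin.

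Exons were included less after apigenin than after luteolin, with 862 calls against 45. A single library would have to carry this, but over the 4 left-out libraries whose fit made calls the ratio of higher to lower events stayed at 15.3 or more, and at unadjusted p under 0.05 it stayed at 6.9 or more over all 6. Medians from the luteolin mean of -5.89 and -8.12 points came from exons at a mean of 20% to 80%, a range that takes in exons that fell with apigenin, so they decide nothing. Over exons at 20% to 80% in DMSO, the medians of both apigenin libraries lay below the luteolin mean, at -3.40 (95% interval -3.93 to -2.78) and -3.88 (-4.58 to -3.39) points, so library depth is unlikely as the source for exons of that range. What set the compounds apart stays open, and their uptake and stability were not analysed here.

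Library medians of intron retention were 0.95 points above DMSO with apigenin and 0.83 with luteolin (exact permutation p = 0.33 for each, the smallest possible), and the authors' deposited table gave 137 introns higher and 135 lower with apigenin and 111 and 110 with luteolin. A large amount of unspliced RNA or genomic DNA in the libraries would raise nearly every intron. Of tested introns, 54.9% (Wilson 95% interval 53% to 56.8%) were higher with apigenin and 55.4% (53.5% to 57.2%) with luteolin, so a large amount is unlikely. A small amount stays open, since counting noise moves introns both ways and the share it would raise was not simulated. The design offers the compounds as the biological explanation, which stays open, with 2 libraries per group.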
